A study of Mus musculus with 12 samples.

How the data were processed

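Neutrophils were obtained from the bone marrow of naive female Balb/c mice and from the blood of mice with liver metastases, the latter divided into high-density and low-density fractions. Per the labels' protocols, total RNA was extracted with TRIzol and column purification, and stranded libraries were made from polyadenylated RNA with a KAPA kit. Per the submitters' processing notes, the reads passed through CASAVA 1.8.2, Trimmomatic and STAR, and DESeq2 1.16.1 was used, with no version given for Trimmomatic and STAR. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are reported and antisense or overlapping genes cannot be told apart.

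The deposited count table held raw counts of 23621 gene symbols in 12 columns, whole numbers that the authors had not normalized, and per the file headers its columns were named like the per-gene count files of STAR. Each column was assigned to a sample by its name, and 0 columns of sample values were left unmatched. The authors also deposited 3 tables of DESeq2 comparisons. Per the file headers these give a mean normalized signal per gene, a log2 fold change with its log2 standard error, a test statistic (a score), and a raw and an adjusted p-value. Values from them are named as the authors' wherever they are printed, and 977 genes with 1 read in total were absent from them.

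Genes were tested on the counts as deposited with edgeR 4.0.16 in R 4.3.3. Of 15762 symbols with reads, 10604 passed edgeR's filter on low counts by group and held 99.967% of all counts. Libraries were scaled by TMM. The mean scaling factor was 1.04 in Naive, 1.09 in HDN, where HDN 7 had 1.28 and the others 1.01 to 1.05, and 0.886 in LDN. A quasi-likelihood model with robust dispersion was fitted to all 12 libraries with group as the only term, and the 3 comparisons between groups were tested at a Benjamini-Hochberg adjusted p under 0.05. Because RNA composition sets the scaling, fold changes are relative to the bulk of genes in each library. Without molecular identifiers, reads are not independent molecules, and floors cover counting error only.

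The groups, the main tests, the alternatives, 42 gene lists with 810 members and the rule for naming genes were fixed before the data were examined. The lists covered neutrophil granules and maturation, cell division, metabolism, effector and signalling functions, and markers of other cell types, and 49 members had no row under their symbol. The 36 lists with at least 3 tested members were tested with camera in edgeR and limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation. Members were counted as higher or lower by adjusted p over all genes and adjusted over the list alone. Named genes were the 6 largest differences each way with an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between groups, up to 4 members of each list with a mean log2 CPM of at least 1, a fixed set of neutrophil and metabolic genes, and the most abundant genes. Of the fixed set, Ly6g, Cd274, Aldh18a1 and Cpt1a were not analysed here, and Arg1 and Ppargc1a lay below the filter. Genes named as exceptions to their list (Srgn, Fcgr4, Sc5d, Sdha, Tnf, Ndrg1 and Itga4), the sterol genes and the markers with few reads were chosen after their values were seen. Some genes that the rule allows are not reported here.

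Shares of counts and distances to the Naive mean were compared by exact two-sided permutation over the 70 arrangements of 4 against 4, and for LDN and HDN also by exact sign flips of the 4 pairs. For Nos2 the fold against Naive was also given as the ratio of summed reads per effective library size, with an exact conditional binomial interval at 95%. The overlap of the comparisons against Naive was set beside 20 simulations of unchanged groups and beside splits of the controls into pairs. In the simulations all 12 libraries, Naive included, were drawn around the Naive mean. Principal components were computed on log2 CPM with a prior count of 2.

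HDN and LDN share the replicate numbers 3, 4, 5 and 7 in the labels, which do not say what a number stands for. Deviations from the group mean over the 10604 genes correlated at 0.31 to 0.76 between samples with the same number and at -0.61 to 0.41 between other pairs. Every same-numbered pair was above the minimum of 0.1 set in advance, so the numbers were taken to pair the HDN and LDN samples. The match was not exclusive, as HDN 3 correlated at 0.41 with LDN 5 and at 0.39 with LDN 3. The main fit, fixed in advance, kept group as its only term, and the replicate block was an alternative. The blocked value is printed where it changes the call of a list or of a gene given for that comparison. The replicate numbers of Naive paired with neither group. No 2 libraries of a group were the same library counted again, since the chi-square per gene between replicates was 3.26 to 182, where 1 would mean no difference. The lowest value was that of Naive 3 and Naive 4, and the next lowest was 14.8. These values do not show whether 2 libraries came from the same RNA or pool.

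The test was run on simulated data made from the real means, library sizes and spread over the same genes, with 200 of them changed. In LDN against HDN it recovered 7.46% of genes changed 1.5-fold, 49.3% changed 2-fold and 92.4% changed 4-fold. In HDN against Naive these were 10.4%, 56.7% and 95.5%, and in LDN against Naive 10.4%, 43.3% and 87.9%. A raised list of 30 genes was recovered and 0 of 40 unchanged lists passed. The simulated genes varied independently of each other. This run thus cannot show how the list test behaves where the members of a list vary together.

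Alternatives were RLE scaling, library sizes without the 20 most abundant genes, no filter or a filter of 1 CPM in at least 4 libraries, non-robust dispersion, replicate blocks, DESeq2 1.42.0, limma-voom, only the 8 libraries compared, stricter thresholds, fry in place of camera, and each library left out in turn. Ribosomal protein genes, G6pdx, Hspa1b, Stfa2l1, Hist1h2bc and haemoglobin genes share reads with near-identical copies and are uncertain.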

Results

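RNA sequencing was carried out on neutrophils of female Balb/c mice aged 8 weeks, in 12 libraries that formed 3 groups of 4. The Naive group held neutrophils from the bone marrow of mice without tumours. The other groups came from the blood of mice with liver metastases and held high-density neutrophils (HDN) and low-density neutrophils (LDN). Neutrophils are short-lived white blood cells that mature in the bone marrow, where granule proteins are made in successive waves. Low-density neutrophils stay with the mononuclear cells when blood is separated on a density gradient, whereas high-density neutrophils sink through it. By its title the study concerned immature LDN, their use of fuels and the spread of breast cancer to the liver.

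Total counts per library ranged from 18113922 to 27741885 in Naive, from 20049857 to 30044508 in HDN and from 23181686 to 26456768 in LDN. A level of 3 reads, taken as the floor of detection, was worth 0.0954 to 0.153 CPM (counts scaled to a common library size), a limit that covers counting error only. Expression is given as CPM (mean ± SD, n = 4 per group) after TMM scaling. Differences are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, over 10604 genes. For each gene named as higher or lower, all 4 libraries of one group lay above all 4 of the other unless stated. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

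The 3 groups separated in a principal component analysis. The first component held 66.5% of the variance and placed Naive between -104.4 and -95.14, LDN between 23.89 and 32.73 and HDN between 70.32 and 74.92. The second component, with 17.9%, placed LDN between -55.87 and -44.58 and HDN between 29.19 and 53.23, with HDN 7 at the upper end. Transcripts of S100a8 and S100a9, which encode the subunits of the calcium-binding protein calprotectin, were among the most abundant. S100a9 took 7.23% of counts in Naive, 4.79% in HDN and 7.08% in LDN, and S100a8 took 5.50%, 3.82% and 6.56%. The 10 most abundant genes together held 24.5% ± 0.641 of counts in Naive, 12.7% ± 1.74 in HDN and 20.8% ± 1.39 in LDN. LDN exceeded HDN by 8.11 percentage points (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.0686 after Benjamini-Hochberg adjustment over the shares tested). The share was higher in LDN in all 4 pairs of the same number, by 6.85 to 8.87 points (exact sign-flip p = 0.125, the smallest that 4 pairs allow).

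**Figure D1:**
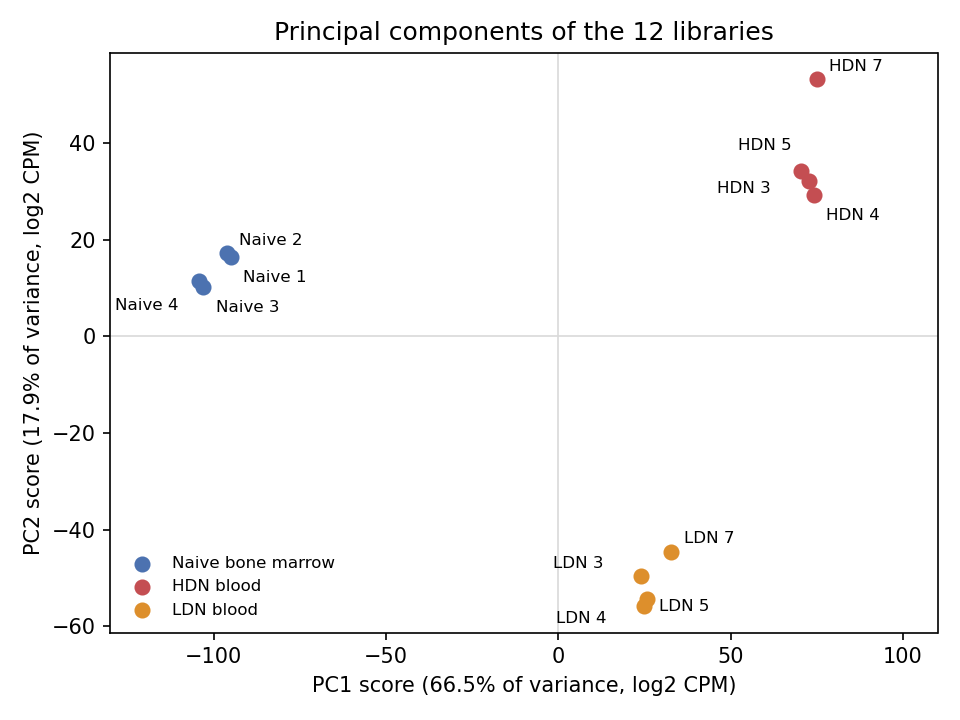
Scores of the 12 libraries on the first (66.5% of variance) and second (17.9%) principal components of log2 CPM, with each point a library coloured by group. Naive lies at the left, HDN at the upper right and LDN at the lower right.

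The comparison of LDN with HDN addressed how the density fractions from the blood of mice with metastases differ. Ltf and Camp, transcripts of secondary granule proteins, were higher in LDN. Ltf, which encodes the iron-binding protein lactoferrin, stood at 12971 ± 3616 CPM in LDN and 696 ± 379.9 CPM in HDN (log2 fold change 4.22 ± 0.44, adjusted p = 8.1e-06). Camp, which encodes the antimicrobial peptide cathelicidin, stood at 1109.8 ± 292.6 CPM against 55.7 ± 29.9 CPM (4.32 ± 0.42, adjusted p = 4.33e-06). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, went the other way, with 174 ± 80.2 CPM in LDN and 960.2 ± 375 CPM in HDN (-2.46 ± 0.35, adjusted p = 8.74e-05). In all, 4914 genes passed the test, of which 2761 were higher and 2153 lower in LDN. The balance turned with the scaling, to 2416 higher and 2689 lower with library sizes taken without the 20 most abundant genes. The libraries of the groups did not overlap for 4162 genes, or 39.2% of those tested, where chance gives 2.86%.

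Of the genes with the largest differences at a mean log2 CPM of at least 4, Fcnb, Camp, Ltf, Fn1, Ccnb2 and Ngp led those higher in LDN. Fcnb, which encodes the pattern-recognition protein ficolin-B, was 22.3-fold higher, Ngp, a neutrophilic granule protein, 11.7-fold, and the extracellular matrix gene Fn1 (fibronectin) 14.0-fold. Atf3, Hist1h2bc, Syt11, Abcg1, Cd101 and Il1b led those lower in LDN. The transcription factor gene Atf3 was 9.27-fold lower, the sterol exporter gene Abcg1 5.90-fold, and Cd101, a surface marker of mature mouse neutrophils, 5.86-fold. Hist1h2bc has near-identical copies in the histone clusters, so its counts are uncertain.

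Most tested members of the secondary and primary granule lists were higher in LDN. Of 14 tested members of the secondary (specific) granule list, 11 were higher and 0 lower in LDN (camera adjusted p = 1.27e-11, and adjusted p = 0.115 with an estimated correlation). Of 9 primary (azurophil) granule members, 7 were higher, among them Mpo (myeloperoxidase, 4.32), Elane (neutrophil elastase, 4.10) and Serpinb1a (an inhibitor of granule proteases, 3.20), and Srgn (the granule proteoglycan serglycin, -0.73) was lower (adjusted p = 0.000533, and adjusted p = 0.235 with an estimated correlation). Mmp8, a collagenase of the secondary granule, was at 4086 ± 484 CPM in LDN and 3962 ± 1315 CPM in HDN (0.04, adjusted p = 0.887). The gelatinase granule list had 5 members higher, led by Lyz2 (lysozyme, 1.93) and Mmp9 (gelatinase B, 0.87), and Fcgr4 lower, and missed the threshold (adjusted p = 0.0579, and 0.0393 with the replicate block). It passed without HDN 3 (adjusted p = 0.0326), HDN 5 (0.0270) or LDN 7 (0.0391), and the Fcgr4 call, for which the groups overlapped, ended without HDN 4 (0.0591). The mature neutrophil list had 8 of 14 members lower and 0 higher, or 8 lower and 1 higher adjusted over the list alone (adjusted p = 1.27e-05, and adjusted p = 0.242 with an estimated correlation). Its lower members included Fgl2 (-2.13), the growth-restraining gene Btg1 (-1.74) and Csf3r, the receptor for granulocyte colony-stimulating factor (-1.13).

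Cell-cycle transcripts were higher in LDN at low absolute levels. Of 29 mitosis genes, 28 were higher and 0 lower (adjusted p = 1.59e-25, and adjusted p = 0.134 with an estimated correlation). Mki67, which encodes the proliferation marker Ki-67, stood at 4.45 ± 0.895 CPM in LDN and 0.335 ± 0.175 CPM in HDN (3.72 ± 0.35, adjusted p = 3.54e-06), and cyclin A2 (Ccna2) was 24.5-fold higher. Of 24 DNA replication genes, 17 were higher and 0 lower, or 18 and 0 adjusted over the list alone (adjusted p = 1.18e-06, and adjusted p = 0.351 with an estimated correlation), with Uhrf1 at 4.21 and the helicase gene Mcm6 at 3.72. Among 12 precursor regulators and surface proteins, 7 were higher and 4 lower (adjusted p = 0.196). The transcription factor genes Cebpe (2.86), Myb (3.44) and Gfi1 (2.93), which act in granulocyte development, were higher. Kit, which encodes the stem cell factor receptor of early progenitors, was lower, at 112 ± 36.6 CPM in LDN and 590.2 ± 181 CPM in HDN (-2.39).

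Among metabolic lists, cholesterol synthesis, pentose phosphate, respiratory chain, glycolysis and glycogen genes were higher in LDN at the preset correlation, and 5 other lists did not pass. The cholesterol synthesis list had 15 of 17 members higher, with Mvk (mevalonate kinase) at 3.25 and Sqle (squalene epoxidase) at 3.09, and Sc5d lower at -0.99 (adjusted p = 8.88e-12, and adjusted p = 0.134 with an estimated correlation). In the pentose phosphate pathway, a source of NADPH, 6 of 8 members were higher, including Tkt (1.25) and Pgd (1.07), as well as G6pdx (1.63), whose reads may be shared with a copy (adjusted p = 0.0192, and adjusted p = 0.467 with an estimated correlation). Of 68 nuclear-encoded respiratory chain and ATP synthase genes, 47 were higher and 0 lower, or 50 and 0 adjusted over the list alone (adjusted p = 7.33e-06, and adjusted p = 0.602 with an estimated correlation), with Ndufv3, a complex I subunit gene, at 1.24. Of 79 cytosolic ribosomal protein genes, whose counts are uncertain because of many processed copies, 65 were higher and 0 lower (adjusted p = 5.28e-11, and adjusted p = 0.351 with an estimated correlation). Their share of counts was 0.754% ± 0.0721 in LDN and 0.587% ± 0.0824 in HDN (difference 0.167, exact permutation p = 0.0571). HDN 4, at 0.709%, was the only HDN library above any LDN library (LDN 5, 0.681%). Without HDN 4 the difference was 0.208 (exact permutation p = 0.0286). That is the smallest p possible there, which leaving out the only overlapping HDN library must give. The share was higher in LDN in all 4 pairs of the same number, by 0.132 to 0.202 points (exact sign-flip p = 0.125).

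Glycolysis genes were higher for 10 of 19 members and lower for 0 (adjusted p = 0.0355, and adjusted p = 0.703 with an estimated correlation), led by the hexokinase gene Hk3 (1.51) and Pgk1 (1.27). The call ended without HDN 7 (adjusted p = 0.0718) or LDN 4 (0.0546). Slc2a1, the glucose transporter GLUT1, was at 287 ± 25.8 CPM in LDN and 288 ± 68.1 CPM in HDN (adjusted p = 0.993). Of 12 glycogen metabolism genes, 6 were higher and 0 lower, with glycogen synthase (Gys1) at 1.47 (adjusted p = 0.0410, and adjusted p = 0.242 with an estimated correlation), and this call ended without HDN 4 (0.0607) or LDN 5 (0.0646). TCA cycle genes were higher for 11 of 22 members and lower for Sdha alone (adjusted p = 0.0579, and 0.0186 without HDN 4). Mitochondrial ribosome genes were higher for 16 of 70 and lower for 4 (0.196, and 0.0186 without HDN 4). Fatty acid oxidation genes were higher for 7 of 17 and lower for 0 (0.224), and mitochondrial biogenesis genes higher for 4 of 13 and lower for 1 (0.701). In the glutamine, glutamate and proline list, 3 of 16 members were higher and 3 lower, among them Oat (-0.98; adjusted p = 0.961 for the list). Glud1 was at 0.23 (adjusted p = 0.0705, and 0.0389 with the replicate block), and Prodh at 0.43 (0.494).

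Effector and signalling lists divided. The NADPH oxidase and extracellular trap list had 9 of 11 members higher in LDN, or 10 adjusted over the list alone, and 0 lower (adjusted p = 0.000144, and adjusted p = 0.271 with an estimated correlation). It shares Mpo and Elane with the primary granule list, so the results of these lists are not separate. Its median log2 fold change was 0.653 and its mean 1.58. Cybb, the catalytic oxidase subunit, stood at 983 ± 528 CPM against 120.1 ± 48.1 CPM (3.03), and Padi4, which citrullinates histones, was 3.36-fold higher. Inflammatory cytokine genes were lower for 10 of 16 members, including the macrophage growth factor gene Csf1 (-2.29) and Ptgs2, the inducible cyclooxygenase, whose libraries overlapped (-3.34), and Tnf was higher at 0.83 (adjusted p = 0.000203, and adjusted p = 0.235 with an estimated correlation). Interferon-stimulated genes were lower for 13 of 20 members and higher for 0, with Oasl2 at -2.08 and Rsad2, whose libraries overlapped, at -1.55 (adjusted p = 0.00215, and adjusted p = 0.536 with an estimated correlation). Hypoxia genes were lower for 7 of 14 members, including Pdk1 (-2.05), Bnip3 (-1.61) and P4ha1 (-1.09), and Ndrg1 was higher at 0.87 (adjusted p = 0.0189, and adjusted p = 0.242 with an estimated correlation). Immediate-early and heat-shock genes were lower for 8 of 15 and higher for 0 (adjusted p = 0.000989, and adjusted p = 0.467 with an estimated correlation). In the adhesion and chemotaxis list, 7 of 18 members were higher and 5 lower (0.703), with the marrow retention receptor gene Cxcr4 at -1.41 and Cxcr2 at -0.31 (adjusted p = 0.215, and 0.0279 with the replicate block). Suppressor-cell genes were higher for 4 of 15 and lower for 4 (0.755), unfolded protein response genes for 4 and 5 of 17, or 4 and 6 adjusted over the list alone (0.701), and apoptosis regulators for 1 and 5 of 16 (0.0896).

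No list of markers of other cell types passed with TMM scaling and all 12 libraries in LDN against HDN, although single markers did. Monocyte and macrophage markers were higher in LDN for 8 of 13 members, including Fn1 and Ly6c2 (2.21), while Csf1r, the receptor for macrophage colony-stimulating factor, was lower (-1.60; adjusted p = 0.0896 for the list). Platelet markers were higher for 7 of 9, including Itgb3 (2.91), and lower for Itga2b (-1.56). That list missed the threshold with TMM scaling of all libraries (adjusted p = 0.0516, and adjusted p = 0.242 with an estimated correlation), and passed with RLE scaling of all libraries (0.0420) and without HDN 3 (0.0326), HDN 7 (0.0210), LDN 3 (0.0424), LDN 4 (0.0436), LDN 5 (0.0478) or LDN 7 (0.0306). B cell markers were higher for 2 of 8 and lower for 0 (0.196), dendritic cell markers for 2 and 0 of 4 (0.516) and basophil markers for 2 and 0 of 3 (0.281). Of 5 eosinophil markers, 2 were lower, among them Siglecf (-1.84), and 0 higher, or 2 and 1 adjusted over the list alone (0.281). Of 9 T cell markers, Cd3d was higher and 0 lower (2.10; 0.570 for the list), and Cd3g, at 0.86 (adjusted p = 0.115), passed with the replicate block (0.0330) and without HDN 5 (0.0288). Pro-B cell and plasma cell lists had 0 members that passed, of 4 and 3 (0.868 and 0.770). Haemoglobin genes, erythroid, natural killer, hepatocyte, epithelial, stromal and mitochondrially encoded genes had fewer than 3 usable members with all 12 libraries and were not analysed here as lists of that set.

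**Figure D2:**
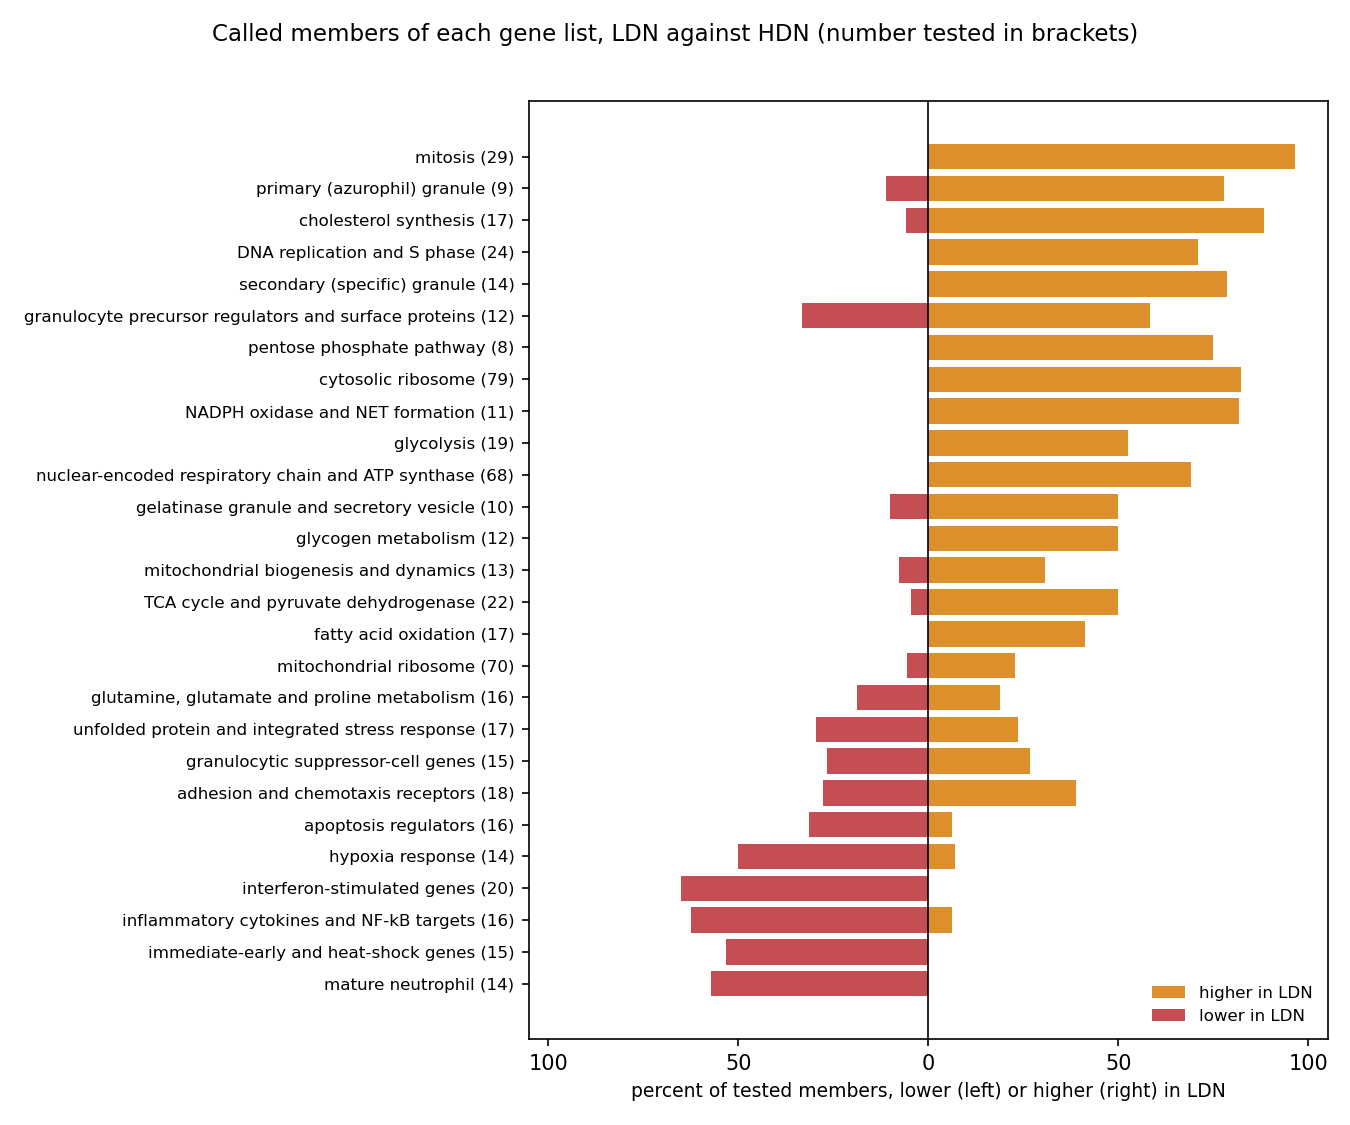
Percent of tested members higher (right) or lower (left) in LDN than in HDN, by edgeR adjusted p under 0.05, for each gene list of neutrophil functions, ordered by the median log2 fold change of its members. Mitosis, with 28 of 29 members higher, lies at the top, and the mature neutrophil list, with 8 of 14 members lower, at the bottom.

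Of 36 lists tested, 16 passed in LDN against HDN with the preset correlation of 0.01 and 0 with an estimated one. Median, mean and test differed in sign for the glutamine, suppressor-cell, adhesion, unfolded protein, plasma cell, T cell and eosinophil lists.

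The comparison of HDN with Naive set blood neutrophils of mice with metastases against marrow neutrophils of mice without them, so that tissue and tumour changed together. Saa3, which encodes an acute-phase serum amyloid protein, stood at 8148 ± 4375 CPM in HDN and 2.64 ± 0.632 CPM in Naive (11.6 ± 0.80, adjusted p = 3.61e-08). Nos2, the inducible nitric oxide synthase, stood at 279 ± 72.5 CPM against 0.129 ± 0.0274 CPM (11 ± 0.37, adjusted p = 1.33e-10). Its Naive level, 12 reads in all and 2 to 4 per library, lay at the floor of detection, and the ratio of summed reads had a 95% exact counting interval of 1270.3-fold to 4295-fold. Camp fell from 8064 ± 773 CPM in Naive to 55.7 ± 29.9 CPM (-7.18 ± 0.48, adjusted p = 2.45e-08), and Mki67 from 49.5 ± 12.6 CPM to 0.335 ± 0.175 CPM (-7.19 ± 0.36, adjusted p = 2.76e-09). In all, 6344 genes passed, of which 3177 were higher and 3167 lower in HDN, and the libraries did not overlap for 5653 genes, or 53.3% (chance, 2.86%). This even balance moved with the processing, to 3503 higher and 2995 lower without the 20 most abundant genes, 3471 and 3630 with DESeq2 and 3035 and 3231 with limma-voom. The 8 HDN and LDN columns of the count table also carried a date-like tag that no Naive column had, so a library batch cannot be separated from the groups.

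Of the genes with the largest differences, Wfdc17 was 389-fold and Lipg, which encodes endothelial lipase, 347-fold higher in HDN, and Mmp19 (10.4) and Igfbp6 (9.02) were also among them. Fcnb was 171-fold lower and Hvcn1, the voltage-gated proton channel of the phagocyte, 97.4-fold lower, and Tinagl1 (-5.61) and Itgb3 (-5.00) followed. Secondary granule genes were lower for 11 of 14 members, including Ngp (-4.17) and Ltf (-4.92), and higher for 1, or 2 adjusted over the list alone (camera adjusted p = 4.55e-05, and adjusted p = 0.202 with an estimated correlation). Mature neutrophil genes were higher for 8 of 14 and lower for 0 (adjusted p = 0.000694, and adjusted p = 0.400 with an estimated correlation), with the interferon-inducible Ifitm1 at 5.96 and the decoy receptor gene Il1r2 at 3.95. Mitosis genes were lower for 28 of 29, or all 29 adjusted over the list alone (adjusted p = 4.28e-33, and adjusted p = 0.131 with an estimated correlation), and DNA replication genes for 23 of 24 (adjusted p = 1.19e-14, and adjusted p = 0.202 with an estimated correlation). Precursor genes were lower for 8 of 12, with Myb at -6.77 and Cebpe at -4.66, while Kit (5.74) and the integrin gene Itga4 (2.45) were higher (adjusted p = 0.00176, and adjusted p = 0.131 with an estimated correlation). Kit stood at 590.2 ± 181 CPM in HDN and 11.1 ± 2.67 CPM in Naive.

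Hypoxia genes were higher for 10 of 14 and lower for 3, with the prolyl hydroxylase gene P4ha1 at 3.11 and Pdk1, which restrains pyruvate entry into the TCA cycle, at 3.68 (adjusted p = 0.0121, and adjusted p = 0.202 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 39 of 79 and lower for 3 (adjusted p = 0.0129, and adjusted p = 0.906 with an estimated correlation), a call that ended without HDN 4 (0.0548). Their share of counts was 0.348% ± 0.0172 in Naive (HDN minus Naive 0.239, exact permutation p = 0.0286, 0.0686 adjusted). B cell markers were lower for 8 of 8, with Cd79a at -4.72 (adjusted p = 0.0121, and adjusted p = 0.740 with an estimated correlation), and platelet markers lower for 7 of 9 and higher for 1, Itga2b (adjusted p = 0.0117, and adjusted p = 0.202 with an estimated correlation). These marker changes went with the lower granule and mitosis transcripts of HDN.

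Other lists did not pass in HDN against Naive, although many of their members did. In glycolysis, 7 of 19 members were higher, including Slc2a1 (2.47) and Pfkl (1.79), and 5 lower, including the hexokinase gene Hk2 (-2.36; adjusted p = 0.460 for the list). Oat (2.29) was among 9 of 16 glutamine list members that were higher, against 4 lower (0.600), and Prodh, which begins proline breakdown, was 45.7-fold lower. Acadl, of fatty acid oxidation, was 7.43-fold higher (list 7 higher and 4 lower of 17, or 7 and 5 adjusted over the list alone, 0.373). Respiratory chain genes were lower for 26 of 68 and higher for 3, or 23 and 2 adjusted over the list alone (0.254, and 0.0227 without HDN 4), and mitochondrial ribosome genes lower for 27 of 70 and higher for 11 (0.415). Cholesterol synthesis genes were lower for 8 of 17 and higher for 4 (0.685), pentose phosphate genes lower for 6 of 8, or 7 adjusted over the list alone (0.0686), and primary granule genes lower for 6 of 9 and higher for 2 (0.301). Interferon genes were higher for 9 of 20, with Oasl2 at 4.43, and lower for 3 (0.235, and 0.0213 with the replicate block), and NADPH oxidase genes lower for 6 of 11 and higher for 2, with Cybb at -2.96 (0.0686, and 0.0224 with the block). Adhesion genes were higher for 10 of 18, with the chemokine receptor genes Cxcr1 at 4.62 and Cxcr2 at 1.47, and lower for 2, including Cxcr4 at -2.22 (0.0951, and 0.0290 without HDN 7). Pro-B cell markers were lower for 4 of 4 (0.0561, and 0.00453 without Naive 1 or 0.05 without HDN 5), and monocyte markers lower for 8 of 13 and higher for 2, or 3 adjusted over the list alone (0.0686, and 0.0455 without Naive 1). Erythroid genes, with 4 or 5 usable members when Naive 1 or any single HDN library was left out, were each time lower for 4 and higher for 0. As a list they passed without Naive 1 (adjusted p = 0.00118, and adjusted p = 0.215 with an estimated correlation) and missed the threshold without HDN 3 (0.123), HDN 4 (0.161), HDN 5 (0.148) or HDN 7 (0.155). The list had too few usable members whenever Naive 2, Naive 3 or Naive 4 was left out. Most of these members thus passed the filter through reads in those Naive libraries, which nearly fixed in advance that they were lower in HDN. Median, mean and test differed in sign for the TCA cycle, mitochondrial biogenesis, glutamine, fatty acid, suppressor-cell, inflammatory, unfolded protein, immediate-early and T cell lists. In all, 9 of 36 lists passed with the preset correlation and 0 with an estimated one.

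The comparison of LDN with Naive asked the same of the low-density fraction, again with tissue and tumour changing together. Nos2 stood at 343 ± 102 CPM in LDN and 0.129 ± 0.0274 CPM in Naive (11.3 ± 0.37, adjusted p = 1.61e-10, with a 95% exact counting interval of 1511-fold to 5108-fold), and Saa3 at 1916 ± 1459 CPM against 2.64 ± 0.632 CPM (9.51 ± 0.74, adjusted p = 2.64e-07). Cxcr4, which retains neutrophils in the marrow, was at 65.6 ± 3.44 CPM against 815 ± 138 CPM (-3.64 ± 0.14, adjusted p = 4.54e-10). Lipg was 602-fold and Wfdc17 340.0-fold higher, whereas Hcar2, a receptor for hydroxybutyrate, was 23.2-fold and Dusp6, a phosphatase of ERK kinases, 14.0-fold lower. In all, 5750 genes passed, of which 2910 were higher and 2840 lower in LDN, and the libraries did not overlap for 5861 genes, or 55.3% (chance, 2.86%). This balance also turned, to 2696 higher and 2994 lower with RLE scaling, 2759 and 2965 without the 20 most abundant genes, 2891 and 3337 with DESeq2 and 2814 and 2839 with limma-voom.

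Granule genes divided in LDN against Naive. Ltf did not pass (-0.70, adjusted p = 0.144, and 0.0283 with the replicate block), although its libraries did not overlap, and Camp was 7.27-fold lower. Secondary granule genes were higher for 5 of 14 and lower for 4 (0.721), and primary granule genes higher for 4 of 9 and lower for 3 (0.491), with Prtn3 (proteinase 3) at 1.21 and Mpo at -1.76. Mitosis genes were lower for 29 of 29 (adjusted p = 7.87e-17, and adjusted p = 0.392 with an estimated correlation), with Mki67 at -3.47, and DNA replication genes for 23 of 24 (adjusted p = 2.28e-10, and adjusted p = 0.392 with an estimated correlation). Precursor genes were lower for 8 of 12, including Gfi1 (-4.61), and higher for 3, including Kit (3.34; adjusted p = 0.00395, and adjusted p = 0.194 with an estimated correlation). B cell markers were lower for 6 of 8, or 7 adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.763 with an estimated correlation), and pro-B cell markers for 4 of 4 (adjusted p = 0.0307, and adjusted p = 0.679 with an estimated correlation).

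Cholesterol synthesis genes were higher in LDN than in Naive for 15 of 17 members and lower for 0 (adjusted p = 1.1e-05, and adjusted p = 0.392 with an estimated correlation), with Fdps (farnesyl diphosphate synthase) 9.88-fold and Sqle 4.60-fold higher. Glycolysis genes were higher for 12 of 19, or 13 adjusted over the list alone, including Aldoc (3.53), Slc2a1 (2.47) and Pfkl (1.75), and lower for Hk2 (-2.07; adjusted p = 0.0123, and adjusted p = 0.763 with an estimated correlation). Fatty acid oxidation genes were higher for 9 of 17, with Acadl 9.43-fold higher, and lower for 2 (adjusted p = 0.0429, and adjusted p = 0.763 with an estimated correlation), a call that ended without Naive 2 (0.0592) or LDN 4 (0.0551). Cytosolic ribosomal protein genes were higher for 70 of 79 and lower for 0 (adjusted p = 1.16e-16, and adjusted p = 0.503 with an estimated correlation), and their share of counts was higher by 0.406 percentage points (exact permutation p = 0.0286, 0.0686 adjusted). Respiratory chain genes were higher for 23 of 68 and lower for 2, or 16 and 0 adjusted over the list alone (0.143).

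Inflammatory genes were lower in LDN than in Naive for 9 of 16, with Ptgs2 at -7.83 and Il1b at -2.01, and higher for 3 (0.0617, and 0.00568 with the replicate block). The list passed without Naive 3 (0.0284), Naive 4 (0.0274) or LDN 7 (0.0311). Immediate-early genes were lower for 8 of 15, including Atf3 (-3.20), and higher for 2 (0.0629), and passed without Naive 3 (0.0176), Naive 4 (0.0252) or LDN 7 (0.0130). Adhesion genes were higher for 11 of 18, with Cxcr1 at 3.30, and lower for 1 (0.0629, and 0.0490 with the block), and passed without LDN 4 (0.0393) or LDN 7 (0.0311). Without Naive 1 the plasma cell list, lower for 2 of 3, and the eosinophil list, lower for 4 of 5 and higher for 1, passed (0.0179 and 0.0167). The erythroid list, then with 5 of 5 members lower, passed without Naive 1 (adjusted p = 0.000142, and adjusted p = 0.207 with an estimated correlation) and, with the same tally, missed the threshold without LDN 3 (0.0720), LDN 4 (0.0875), LDN 5 (0.102) or LDN 7 (0.0613). Most of its members again passed the filter through reads in Naive libraries, which nearly fixed in advance that they were lower in LDN. The remaining lists did not pass, and median, mean and test differed in sign for the primary granule, mature neutrophil, pentose phosphate, mitochondrial ribosome, glutamine, NADPH oxidase, suppressor-cell, interferon, unfolded protein, apoptosis and T cell lists. Of 36 lists, 9 passed with the preset correlation and 0 with an estimated one, and 16 passed without Naive 1 and HDN 7, a choice made after the data were seen.

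**Figure D3:**
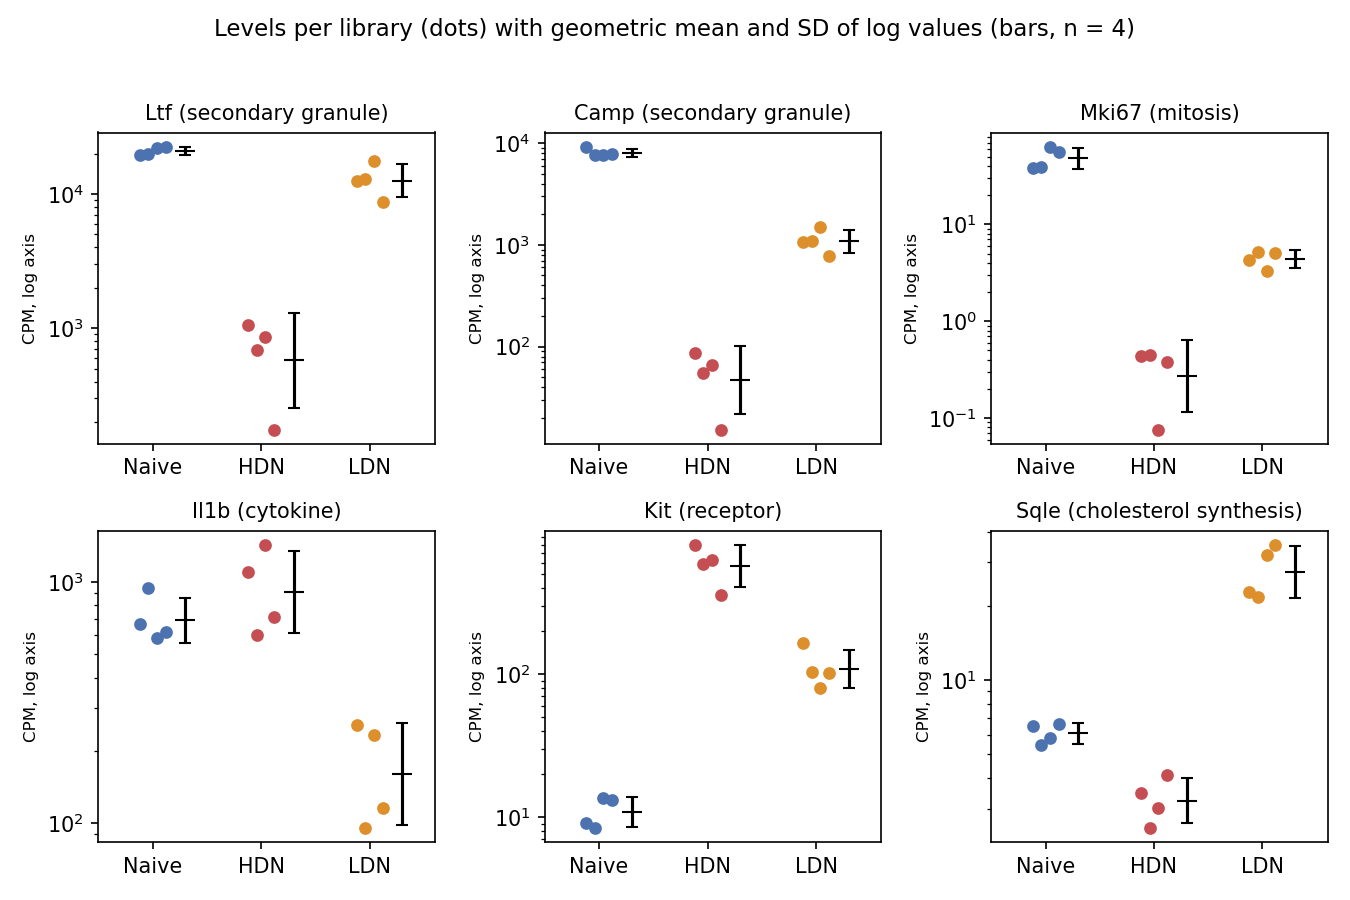
CPM on a log axis for Ltf, Camp, Mki67, Il1b, Kit and Sqle, with each dot a library and each bar the geometric mean ± SD of the log values of 4 libraries. Ltf, Camp and Mki67 lie highest in Naive and lowest in HDN, Kit lies highest in HDN, and Sqle lies highest in LDN.

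Comparing both blood groups with the same marrow libraries, 3971 genes passed in the same direction in HDN and LDN, 1974 higher and 1997 lower, where independent lists of these sizes would share 872 and 848. Nos2, Saa3 and Lipg were among those higher in both, and Camp, Mki67 and Cxcr4 among those lower in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.828 and a covariance of 2.49. In 20 simulations all 12 libraries, Naive included, were drawn around the Naive mean, and both unchanged groups were set against the same simulated controls. The mean correlation was 0.507 and the mean covariance 0.0518. These draws gave 0 shared calls, which is nearly certain where no gene is changed, so that 0 is no baseline for the 3971 genes. With the Naive libraries split 2 and 2 between the comparisons in all 6 ways, 3048 to 3173 genes were shared and the correlation was 0.781 to 0.827. The mean distance to the Naive average over all tested genes was 1.43 ± 0.0284 log2 units for LDN and 1.74 ± 0.0438 for HDN (difference -0.32, exact two-sided permutation p = 0.0286, the smallest of 70 arrangements). With LDN and HDN taken as 4 pairs the exact sign-flip p was 0.125, the smallest that 4 pairs allow.

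By their order between groups, 969 genes were higher in LDN than in both other groups, 805 lower than in both, 1222 highest and 1757 lowest in HDN, each by both tests. LDN lay between the others for 826 genes with Naive highest, such as Camp, and for 425 with HDN highest, such as Kit.

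In the authors' deposited table for LDN and HDN, 5456 of 14785 genes had an adjusted p under 0.05, of which 4776 also passed here in the same direction. The authors' deposited table for HDN and Naive held 7168 such genes, with 6306 shared, and the authors' deposited table for LDN and Naive 6234, with 5581 shared. No gene passed in opposite directions, and the log2 fold changes of each of the authors' deposited tables had a Pearson correlation of 0.995 with those computed here, across genes.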

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

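The tests of scaling, maturity, cycling cells of another lineage and the column tag, and the splits of the LDN and HDN libraries, were chosen only after the results were seen. A library was singled out where its gap to the nearest of its group, as a share of the group's range, was above the 95% critical value of Dixon's test. This held for 23 of 390 groups of values, where chance gives about 19.5.

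In Naive 1, log2 CPM was high for Camp (13.2, others 12.9), Tkt (11.1, others 10.8), S100a9 (16.3, others 16), Pfkl (4.78, others 4.53 to 4.54), Srebf2 (7.45, others 7.02 to 7.06) and Lpcat3 (5.36, others 5.06 to 5.11) and low for Cd79a (2.56, others 3.66 to 3.74). Its share of counts from the ribosomal precursor Rn45s was 1.36%, against 0.242% to 0.324% in the other Naive libraries. Naive 2 was high for Ptgs2 (6.18, others 5.52 to 5.59). HDN 7 was low for Itgb3 (0.298, others 2.02 to 2.26), Igfbp6 (6.74, others 7.81 to 7.96) and Hvcn1 (0.506, others 1.5 to 1.68) and had a scaling factor of 1.28 against 1.01 to 1.05. HDN 4 was low for Ccr2 (-0.917, others 1.5 to 1.95) and Abca1 (5.49, others 6.52 to 6.72). HDN 5 was low for Mki67 (-2.64, others -1.1 to -0.917) and, for Pf4, held the 2 reads counted in HDN (-2.64, others -3.56, the value of 0 reads). LDN 4 was high for Rpl32 (8.09, others 7.69 to 7.73), Aldoc (3.39, others 3.17 to 3.2) and Pfkl (6.68, others 6.17 to 6.24). LDN 5 was low for Fn1 (6.74, others 7.56 to 7.7) and LDN 7 for Cd3e (-1.66, others -0.188 to 0.0771). LDN 3 lay nearest to the Naive mean (1.38, others 1.43 to 1.44).

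A set of 241 genes passed in opposite directions in HDN and LDN against Naive, and 108 to 206 did with the Naive libraries split between the comparisons. All 241 also passed in LDN against HDN, which such a choice of genes makes nearly certain. Of these, 144, such as Sqle, Mvk and Serpinb1a, were highest in LDN and lowest in HDN, and 97 were highest in HDN and lowest in LDN.

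Of 14 secondary granule and 29 mitosis genes, 11 and 28 were higher in LDN than in HDN (camera adjusted p = 1.27e-11 and 1.59e-25, and adjusted p = 0.115 and 0.134 with an estimated correlation), with a median log2 fold change of 1.67 over all 14 granule members, 3.73 over all 29 mitosis members and 3.55 over the 39 called ones. A shift of the scaling by the 20 most abundant genes is argued against as the main source. Library sizes taken without them moved the log2 fold changes of all genes by a median of only -0.107. The medians above were then 1.55, 3.62 and 3.46. All 39 still passed, which adds little, since they were picked as called in these data and so small a shift could hardly undo them. A larger share of immature neutrophils in LDN may account for the pattern, since the median of the mature neutrophil list was -1.02 in the same comparison. That list shares Il1b and Junb with the inflammatory and immediate-early lists, so its fall does not speak to maturity alone. The list of precursor regulators and surface proteins did not pass, with 7 of 12 members higher and 4 lower (camera adjusted p = 0.196). Its members Cebpe, Myb and Gfi1 were higher in LDN and Kit and Cxcr4 lower, so this explanation stays open. Cycling cells of another lineage stay open for the mitosis genes. Summed CPM of lymphoid, erythroid, basophil and platelet markers was 189 higher in LDN, beside 171 for the mitosis genes. The SD of that difference was 757 between single libraries, most of it from Hdc, which neutrophils also express. Without Hdc the sum was 85.19 ± 15.8 CPM in LDN and 30.69 ± 10.7 CPM in HDN, or 54.5 higher. Of this Cd3d gave 26.6, Itgb3 22.9 and the other markers together 4.94.

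Some macrophage, platelet and basophil genes were higher in LDN than in HDN, many at very few reads, although with TMM scaling their lists missed the threshold (adjusted p = 0.0896, 0.0516 and 0.281). Of the abundant members Fn1, Ly6c2 and Itgb3 were higher, Csf1r was lower, and Hdc did not pass (adjusted p = 0.747). C1qc, a complement gene of macrophages, had 63 reads in Naive, 0 in HDN and 12 in LDN, Pf4 (platelet factor 4) had 61, 2 and 27, and the mast cell and basophil protease genes Mcpt8 and Prss34 had 80, 4 and 30 and 88, 3 and 33. Among 41 markers of other cell types with a mean log2 CPM under 0, 34.1% were higher in LDN and 7.32% lower, against 24.1% and 21.2% of all 1535 tested genes in that range. RNA of other cells in LDN may account for it, as density separation leaves mononuclear cells beside LDN, and stays open, since the markers near the floor are few and the abundant ones went both ways.

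The blood groups differed from Naive in 6344 genes (HDN) and 5750 genes (LDN), with Nos2 and Saa3 among the largest differences in both. Tissue, tumour and a library batch marked by the column names cannot be told apart here, since the date-like tag was on all 8 blood columns and no Naive column. Saa3 and Nos2 may respond to the tumour, to blood or to handling, and no value decides.

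Other splits of the same libraries were also tried. For HDN against Naive, 1 of 35 splits, the real one, reached 6344 genes and the highest other reached 0. The same held for LDN against Naive, with 5750 genes, 1 of 35 splits and a highest other of 0. This is the smallest share that 35 splits allow. Every other split mixes libraries of both groups, which turns a large group difference into spread within groups and leaves few calls. The counts of 0 thus do not show how often chance alone gives calls, and they do not exclude it. For lists chance is not excluded either. There 19 of 35 splits reached the 9 lists of HDN against Naive and 15 of 35 the 9 of LDN against Naive, with a highest other of 13 in each. For LDN against HDN, the 8 splits that part all 4 pairs are too few for a share under 0.05. The real split gave 4914 genes and the highest other 0, and 3 of the 8 splits reached the 16 lists, with a highest other of 23.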

How the results depend on the processing

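The alternative without Naive 1 and HDN 7 and the pairing of the shares of counts were chosen only after the data were seen. Each gene count stayed within 1.5 times its value under all scalings, filters, tools and blocks tried and with each library left out, except at an added 2-fold threshold, which left 2511 genes in LDN against HDN, 3798 in HDN against Naive and 3218 in LDN against Naive by the construction of the threshold. Without single libraries these counts ranged from 4425 to 5199, 5843 to 6605 and 5133 to 5621, and no gene that passed both as reported and in one of these alternatives changed direction, the one without Naive 1 and HDN 7 included. DESeq2 called 5445, 7101 and 6228 genes and limma-voom 4796, 6266 and 5653. With library sizes taken without the 20 most abundant genes, the median log2 fold change of LDN against HDN shifted by -0.107 and 47.3% of its calls were higher in LDN, against 56.2%.

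With an estimated correlation, 0 lists passed in LDN against HDN, 0 in HDN against Naive and 0 in LDN against Naive, and with fry, which does not compare a list with other genes, 25, 24 and 23 passed. Leaving out single libraries gave 16 to 18, 9 to 12 and 8 to 12 lists. Without Naive 1 and HDN 7, 16 lists passed in LDN against Naive in place of 9, and the cause was not tested. The genes called then numbered 4944, 6347 and 5982. The replicate block for HDN and LDN called 6187, 7264 and 6813 genes and 17, 11 and 11 lists, and a block over all 3 groups called 5482, 5654 and 5106 genes. Of 126 genes named or examined, the block for HDN and LDN brought 8 past the threshold in LDN against HDN, 2 in HDN against Naive and 8 in LDN against Naive, and it changed no other call of these genes. Taken as pairs, the difference in distance of -0.32 had an exact sign-flip p of 0.125, the smallest possible, as did the differences of 8.11 in the share of the top 10 genes and 0.167 in the ribosomal protein share. Without single libraries that difference was -0.33 to -0.298, the share of the top 10 genes differed by 7.31 to 8.65, and the shared calls against Naive numbered 3545 to 4346. The ribosomal protein share of LDN minus HDN was 0.28 (exact permutation p = 0.0286) among counts without the 10 most abundant genes and 0.134 to 0.208 without single libraries, and the cause was not tested.

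With each library left out in turn, 6 named genes lost a call in LDN against HDN, 6 in HDN against Naive and 11 in LDN against Naive, among them Ngp (-0.63, adjusted p = 0.0381, and 0.0724 without Naive 3) and S100a8 (0.48, 0.0477, and 0.167 without LDN 5) in the last. The Ngp call also ended without Naive 2, Naive 4, LDN 3 or LDN 7. That of S100a8 ended without any library of either group other than Naive 1, and with RLE scaling (adjusted p = 0.0729). In simulations with 200 changed genes most of those changed 1.5-fold were missed. The limit is looser where more genes change, and 977, 982 and 969 of the genes called had an estimated change under 1.5-fold.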

Other observations

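The tests of a mixture and of T cells were chosen only after the results were seen. The single genes Abca1, Abcg1, Apoe and Mylip, picked after their values were seen and not tested as a set, were lower in LDN than in HDN. Srebf2 was higher. Abca1 and Abcg1, which export cholesterol, were at -2.16 and -2.56, Apoe, which carries it, at -2.08, and Mylip, a ubiquitin ligase gene, at -2.18. Srebf2, the transcription factor gene of sterol synthesis, was at 1.30, whereas Insig1, which restrains that factor, was at 0.38 (adjusted p = 0.0945, with 0.0154 under the replicate block and 0.0190 without HDN 7). Abca1 was also 7.32 log2 units higher in HDN than in Naive. Some markers went against their lists and were higher in HDN than in LDN, with Kit at 590.2 CPM against 112, the monocyte gene Csf1r at 367 against 122 and Itga2b, a megakaryocyte integrin, at 6.84 against 2.31. In the same lists 7 of 12 precursor, 8 of 13 monocyte and 7 of 9 platelet members were higher in LDN, and Csf1r and Itga2b were the only members of theirs that were lower.

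Less activity of the liver X receptors, which sense oxidised sterols, is a candidate explanation of the sterol pattern. Nr1h3, a target gene named in advance for this, was not among the genes tested. The explanation was tested on 5 other target genes named before they were looked at. Of these, 2 were lower in LDN (Arl4c at -2.05 and Smpdl3a at -0.38, the latter not without HDN 3, where adjusted p was 0.0578), 0 were higher, and Srebf1 (-0.10), Lpcat3 (0.21) and Pltp (-0.62) did not pass, although Pltp did with the replicate block (adjusted p = 0.0455). Without HDN 4 Lpcat3 passed as higher (0.46, adjusted p = 0.0418), and without LDN 5 Pltp passed as lower (-0.81, 0.0486). So few targets leave the explanation open.

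LDN lay between Naive and HDN for many genes, and a mixture of HDN-like and marrow-like cells might produce that. A mixture cannot exceed both of its parts, yet 307 genes were at least 2-fold higher in LDN than in both groups by the test. The position of LDN on the way from HDN to Naive also differed between lists. It was taken as the median over only those members that were lower in HDN than in Naive. As mean ± SD over the LDN libraries, it was 68.4% ± 12 for 11 secondary granule genes and 95.7% ± 23.2 for 6 NADPH oxidase genes. It was 14.5% ± 4.11 for 28 mitosis genes and 9.47% ± 9.5 for 8 B cell markers. Camp and Ltf were both lower in LDN than in Naive. Camp passed the test, and Ltf passed only with the replicate block (-0.70, adjusted p = 0.0283), so these members differed in the size of the change and not in direction. A mixture of these particular profiles is thus argued against as the whole account, while a mixture with cells of another state stays open.

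Cd3d, which encodes a subunit of the T cell receptor complex, was counted at 20067 reads in Naive, 839 in HDN and 2988 in LDN. Cd3e had 8, 58 and 62 reads and Cd3g 238, 43 and 64. The lowest ratio of Cd3d to the sum of its partners over the Naive and LDN libraries was 20.2, whereas T cells carry all of these transcripts. A T cell source might have given similar levels of each. T cells are thus argued against as the main source in Naive and LDN. In HDN the ratio was 5.38 in HDN 4, 8.13 in HDN 5, 14.1 in HDN 3 and 20.2 in HDN 7, which leaves T cells open there. Reads of another transcript counted under the symbol, or expression in neutrophils, stay open and were not tested.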
